A study of Mus musculus with 4 samples.

How the data were processed

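Nuclei of cerebellar granule cells came from mice of a NeuroD1 EGFP-Rpl10a reporter line, per the labels. Each sort drew on the cerebella of 4 mice, with 2 of each sex, and nuclei with high green fluorescence were collected and digested with micrococcal nuclease. Soluble native chromatin was precipitated with an antibody to MeCP2, and input chromatin was sequenced alongside. The 4 libraries formed 2 groups, MeCP2 precipitation with 2 replicates and input with 2 replicates. Nothing in the labels says whether the replicates came from separate pools of animals.

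Per the submitters' processing notes, reads were handled with Bowtie2 2.1.0, SAMtools and HOMER 4.8 on the mm10 build. How each tool was used, how reads were counted over genes and how the libraries were combined is not given in the sources used here. The single deposited table lists 31161 RefSeq transcripts with chromosome, start, end, strand, gene name and 1 column of MeCP2 enrichment, which was treated as a score made by the authors. It was not called a ratio because the header states no denominator and 3 transcripts, of Tunar, Hipk1 and Gm2694, have values below 0, the lowest at -0.990. A further set of transcripts is listed at exactly 0, with a median length of 549 bp. No library size, count or replicate value was analysed here, so no interval or detection floor was computed, and the number of reads behind a short gene is unknown.

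How the value was made could change the measurements. Values of features of at most 150 bp were examined for steps. Of 896 such features above 0, 63.7% equalled a sum of 2 scaled ratios of 2-decimal numbers within a relative tolerance of 3e-06, against a median of 1.34% and a highest value of 4.58% over 100 control scales. A single ratio, with the other term at 0, fitted 38.4%. Values simulated as such sums fitted in 99.3% of cases, so this form leaves a large part of the short features undescribed. This reading comes from the values alone, and no replicate could be read back from it. Transcript starts were equal to the 1-based gene starts for 55.5% of matched transcripts and 1 bp before them for 0.05%, and 98.7% of RefSeq accessions were found in the reference gene table of GRCm38.p6.

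For each of 22685 symbols the longest transcript with a value above 0 was kept, and 340 symbols without such a value were left out, which left 22345 genes on 19 autosomes. Sex-chromosome genes were not analysed here. Before the data were examined, 26 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists were granule cell, housekeeping, Purkinje cell, glial, oligodendrocyte, microglia and endothelial, cortical and interneuron, liver, muscle, immediate early, long synaptic, MeCP2-responsive, DNA methylation and imprinted genes. They also covered Hox, olfactory and vomeronasal receptor, clustered protocadherin, ribosomal protein, histone, keratin-associated protein, major urinary protein, beta-defensin, Zfp, microRNA and small nucleolar RNA genes. The named genes were the 10 highest and 10 lowest of at least 5 kb, the highest, middle and lowest member of each list, and any member of the granule cell, housekeeping and DNA methylation lists. Of the requested members, 14 were not analysed here.

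The design had foreseen a model per gene for values per library. With a single value per gene the branch written for that case was used, so no test between samples was run and no p-value was computed. Each list's median was placed among the medians of 10000 random lists with the same number of genes from each of 10 length bins, and a list was said to stand apart outside the central 95%. Neighbour correlation was set against 1000 random orders of genes within chromosomes. Alternatives covered genes of at least 5 kb, no length matching, no overlapping genes (21.4% of genes overlap another), means over transcripts and no filter on low values. Chosen after seeing the data were 50 length bins, random lists without receptor genes, no filter on low values for the lists, and a rotation of ranks along the genome that keeps neighbours together. Further neighbour settings were also added then.

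The list test was checked on simulated data over 22345 genes. Of 10 lists of 20 genes of at least 5 kb shifted by 0.15, 8 were found in the right direction, and 4 of 60 such unshifted lists fell outside the central 95%. Lists of shorter genes, whose values spread more, were not simulated in this way. When values were simulated with a correlation of 0.6 along the genome, 15 of 60 unshifted lists of 20 adjacent genes fell outside by random lists and 2 by rotation, so calls for clustered families by random lists are too frequent. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.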

Results

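MeCP2, a protein that binds methylated DNA and is abundant in neurons, was mapped in mouse cerebellar granule cells, the small excitatory neurons that send parallel fibres to Purkinje cells. Granule cell nuclei were sorted by the green fluorescence of a ribosomal fusion protein expressed under NeuroD1 control. Native chromatin was then cut with micrococcal nuclease and precipitated with an antibody to MeCP2 without crosslinking (ORGANIC ChIP-seq). The series held 4 libraries, 2 from the MeCP2 precipitation and 2 from the input chromatin. The deposited table gave a single MeCP2 enrichment value for each of 31161 RefSeq transcripts, with mm10 coordinates. Values per library were not analysed here, so the depth is unknown and no value below carries a replicate error. The enrichment centred near 1, but the scale on which the authors computed it is not given in the sources used here, so values are compared with each other only. Differences between groups of genes are set against random lists drawn from the same table, which describes these libraries and is not a test across animals.

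The study addressed how DNA methylation and hydroxymethylation relate to MeCP2 binding in granule cells, and the first comparison concerns how MeCP2 enrichment was spread over genes. Across 22345 gene symbols the median enrichment was 1.01, with quartiles of 0.881 and 1.13. The central bulk was narrow, since 5% of genes lay under 0.673 and 5% over 1.41. Most of the extremes among genes of at least 5 kb had another gene symbol at nearly the same coordinates. The highest was Smok3a, a sperm motility kinase gene on chromosome 5 from 138021276 to 138034659, at 3.91. Its adjacent copy Smok3b, from 138037224 to 138050633, was among the 10 lowest at 0.236. The salivary and pancreatic amylase family was represented by Amy2a2 and Amy2a4, which share coordinates on chromosome 3, at 2.65. Sprr2a1 and Sprr2a2, small proline-rich proteins of the skin barrier, shared a value of 3.11. At the low end stood Hsd3b4, a steroid dehydrogenase gene on chromosome 3, at 0.113, and the overlapping Gm10681, also at 0.113. Of these 20 genes at either end, 13 had a second symbol at the same place within 50 bp, and reads from near-identical copies cannot be assigned with certainty, so these values are uncertain.

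Extremes without such a copy included Slc22a12, the kidney urate transporter gene, at 0.448 and Spata20, a spermatogenesis-associated gene, at 0.451. Among genes of at least 20 kb, a limit chosen after values were seen, the low end held Cmklr1, the chemerin receptor gene, at 0.552 and Rhbdf2, an inactive rhomboid gene, at 0.563. It also held Rtn4r, the Nogo receptor gene, at 0.575, Cxxc5, a CXXC zinc finger gene, at 0.577, and Nfic, a nuclear factor I gene that overlaps another gene, at 0.596. The high end of these longer genes held the vomeronasal receptor genes Vmn2r48 at 1.58 and Vmn2r97 at 1.55. Klra18, a natural killer cell receptor gene, lay at 1.57 and overlaps Klra4 at nearly the same coordinates, so its value is uncertain. Crisp1, an epididymal secretory protein gene, lay at 1.52.

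Genes of the granule cell list, which also holds general vesicle release genes such as Snap25 and Syt1, carried low MeCP2 enrichment. The 30 genes of this list had a median of 0.860, against 1.01 for length-matched random lists, and 28 of the 30 lay below the median of all genes. The lowest were Car4, a membrane-anchored carbonic anhydrase, at 0.601 and Kcnc1, a potassium channel of fast-firing neurons, at 0.643. Rbfox3, the splicing factor known as NeuN, lay at 0.650 and Grin2c, an NMDA receptor subunit of mature granule cells, at 0.658. Mef2d, an activity-dependent transcription factor, lay at 0.663. The presynaptic glutamate receptor gene Grm4 lay at 0.684, the extrasynaptic GABA receptor subunit gene Gabrd at 0.700, and Cacng2, which encodes stargazin, at 0.702. Slc17a7, the vesicular glutamate transporter of parallel fibres, lay at 0.735. The GABA receptor subunit gene Gabra6 at 0.939 and Neurod1 at 0.980 were closer to the median of all genes. The 2 exceptions were Zic1 at 1.18 and Zic2 at 1.47, zinc finger transcription factor genes of the granule cell lineage. The list median fell at percentile 0.02 of 10000 random lists matched on gene length, and it stayed below the central 95% under every alternative run.

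**Figure D1:**
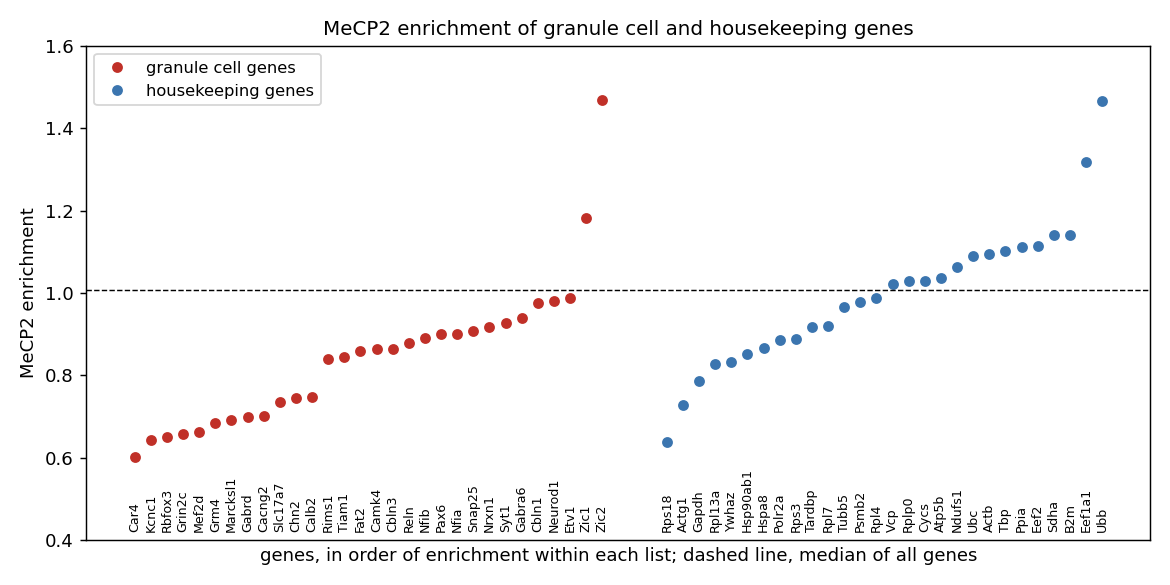
MeCP2 enrichment (vertical axis, the deposited value without unit, from 0.4) of each granule cell gene (red) and each housekeeping gene (blue), in order of enrichment within its list, with the median of all genes as a dashed line. Apart from Zic1 at 1.18 and Zic2 at 1.47 the granule cell genes lie under the dashed line, while the 28 housekeeping genes lie 14 above and 14 below it.

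Housekeeping genes, which granule cells use as other cells do, were not set apart. Their median was 1.01 over 28 genes, at percentile 71.6 of random lists, and 14 lay above and 14 below the median of all genes. The ribosomal protein gene Rps18 was the lowest at 0.638, followed by the cytoplasmic actin gene Actg1 at 0.728 and the glycolytic gene Gapdh at 0.786. The highest were the ubiquitin gene Ubb at 1.47 and the elongation factor gene Eef1a1 at 1.32. The granule cell median lay -0.146 from that of housekeeping genes, a difference at percentile 0.21 of those between length-matched random lists. Of the housekeeping genes, 6 were also members of the ribosomal protein list.

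Genes of other cerebellar cell types, which the sort was designed to leave out, served as a further comparison, and their lists lay inside the range of random lists. Purkinje cell genes had a median of 1.03 (percentile 68.2, 20 genes), from Lhx5, a LIM homeobox gene, at 0.734 to Foxp2, a forkhead factor gene, at 1.27. Bergmann glia and astrocyte genes had a median of 0.979 (percentile 35.6, 18 genes), from the aldolase gene Aldoc at 0.486 to the water channel gene Aqp4 at 1.26. Oligodendrocyte genes had a median of 0.990 (percentile 43.1, 17 genes), from the myelin enzyme gene Cnp at 0.810 to the connexin gene Gjc3 at 1.22. Microglia and endothelial genes had a median of 1.02 (percentile 56.7, 17 genes), from the complement gene C1qa at 0.751 to Tek, the angiopoietin receptor gene, at 1.22. The granule cell median lay below that of each of these 4 lists, by -0.169 for Purkinje cell genes (percentile 0.19), -0.119 for glia (1.67), -0.130 for oligodendrocytes (1.46) and -0.155 for microglia and endothelium (0.74). These 8 comparisons of the granule cell list with other lists share its 30 genes and are not independent.

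Lists of genes of tissues outside the cerebellum were compared in the same way, each with random lists and not with each other. Liver genes had a median of 1.09 over 22 genes, at percentile 98.9, ranging from the apolipoprotein gene Apoa1 at 0.723 to the fibrinogen gene Fga at 1.56, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.11. Muscle genes had a median of 0.963 over 24 genes, at percentile 21.4, from the troponin gene Tnni2 at 0.532 to the myogenic factor gene Myf6 at 1.45. Without overlapping genes the muscle list turned to the high side but stayed inside random lists, with a median of 1.11 at percentile 96.8. Genes of cerebral cortex and interneurons had a median of 0.885 over 21 genes, at percentile 1.72. Their lowest member was Dlx6, a homeobox gene of forebrain interneurons, at 0.561, and their highest Sst, the somatostatin gene, at 1.57. The granule cell median lay -0.025 from that of the cortical list (percentile 24.7) and -0.103 from that of muscle genes (percentile 4.15), both within random lists, while it lay -0.232 from that of liver genes (percentile 0.00). The position of the liver list was lost among genes of at least 5 kb (percentile 97.3) and without length matching (96.9). The position of the cortical list was lost without overlapping genes (10.2), with means over transcripts (2.54) and without receptor genes in the random lists (2.79).

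**Figure D2:**
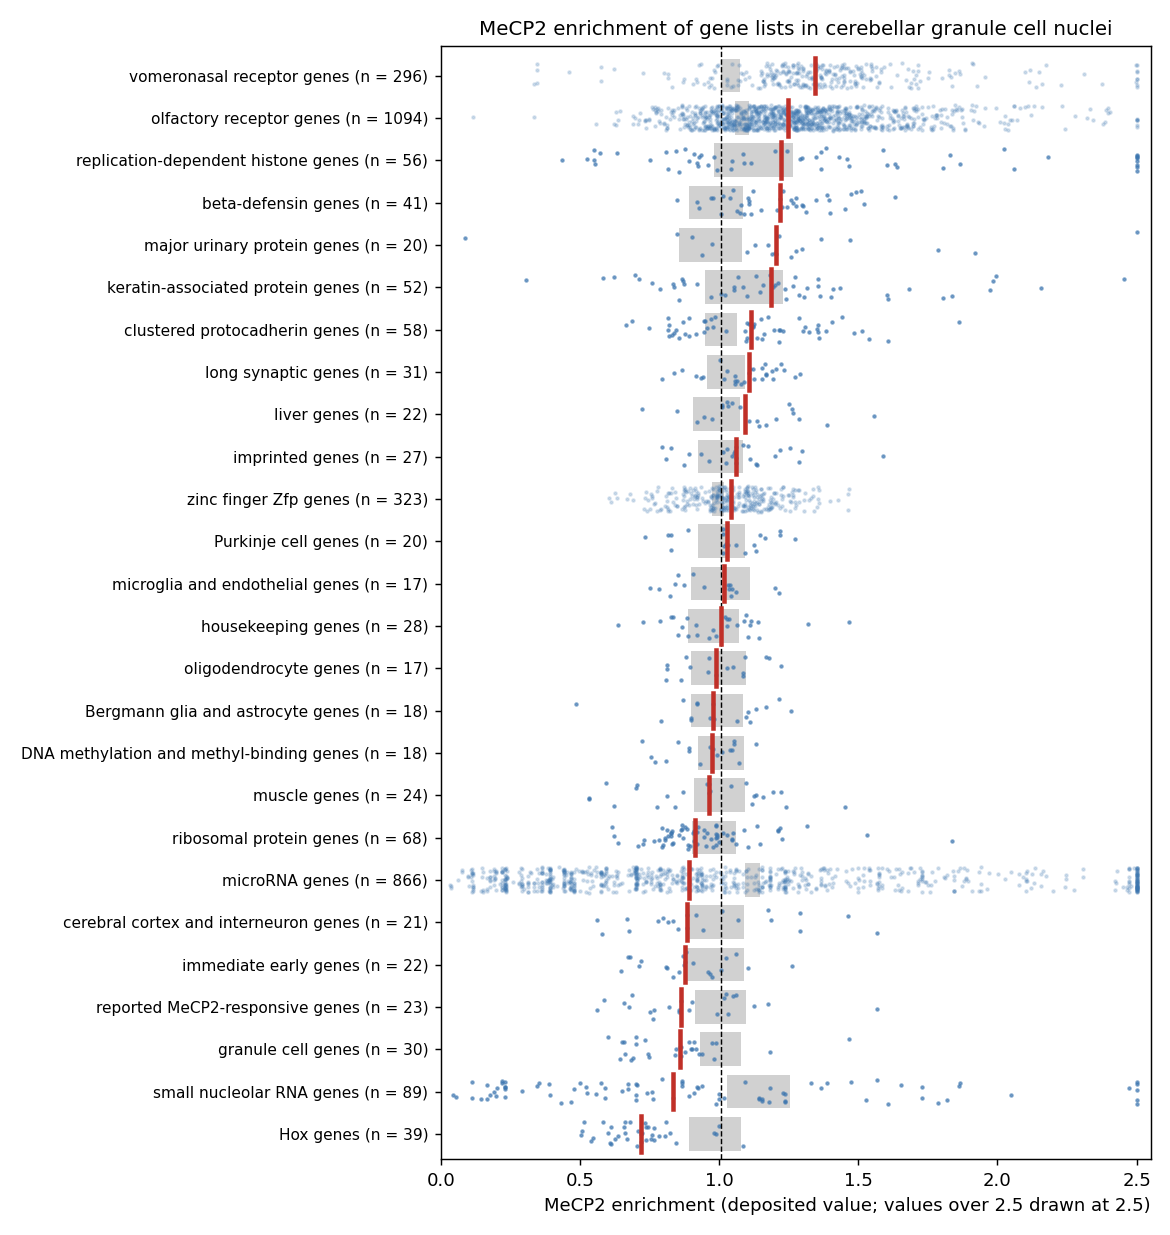
MeCP2 enrichment (horizontal axis, the deposited value without unit, values over 2.5 drawn at 2.5) of every gene (blue points) in the 26 gene lists, ordered by list median (red bars). Grey boxes span the central 95% of medians of length-matched random lists and the dashed line is the median of all genes; the Hox genes sit lowest at 0.718 and the vomeronasal receptor genes highest at 1.35.

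Immediate early genes, which neurons switch on within minutes of activity, had a median of 0.876 over 22 genes, and 18 lay below the median of all genes. Arc, a regulator of glutamate receptor trafficking, was lowest at 0.649, the phosphatase gene Dusp1 stood near the middle at 0.877, and the transcription factor gene Klf4 was highest at 1.26. The list fell at percentile 1.97, but was within random lists among genes of at least 5 kb (34.2), without receptor genes in the random lists (3.88) and with ranks rotated along the genome (2.80). Genes that earlier work on MeCP2 reported as responsive to it had a median of 0.862 over 23 genes, at percentile 0.14. Their lowest member was Dlx6 at 0.561 and the mitochondrial complex III gene Uqcrc1 was in the middle at 0.862, while Sst was highest at 1.57. Among genes of at least 5 kb this list was within random lists, with a median of 0.993 at percentile 30.8. It shared 3 members with the cortical list, 1 with the immediate early list, 1 with the Purkinje cell list and 1 with the imprinted list.

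Very long synaptic and adhesion genes lay above the median of all genes in 24 of 31 cases, with a median of 1.11 at percentile 99.1. Nkain2, on chromosome 10 from 31689319 to 32889915, was highest at 1.29, the netrin-G ligand gene Lrrc4c was in the middle at 1.11, and the adhesion gene Ntm was lowest at 0.796. The position depended on how length was matched. With 50 length bins in place of 10 the percentile was 84.9, and among genes of at least 5 kb it was 97.4.

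Genes of the DNA methylation machinery and methyl-binding proteins lay inside the range of random lists, with a median of 0.974 over 18 genes at percentile 19.9. Dnmt3a, the de novo methyltransferase of neurons, lay at 0.755, Tet3, a 5-methylcytosine dioxygenase, at 0.771 and Zbtb38, a methyl-binding zinc finger gene, at 0.724. The maintenance methyltransferase gene Dnmt1 lay at 1.04, Tet2 at 1.06 and Mbd2 at 0.979. Apobec1, a cytidine deaminase gene, was highest at 1.13. Mecp2 itself is X-linked and was not analysed here. Imprinted genes, which carry methylation on 1 parental copy, had a median of 1.06 over 27 genes at percentile 91.1. They ranged from Dlk1, a Notch ligand gene, at 0.796 to Mkrn3, a ring finger gene, at 1.59.

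Hox genes, the body-axis regulators kept silent in cerebellar neurons, carried the lowest enrichment of the 26 lists. Their median was 0.718 over 39 genes, against 0.982 for length-matched random lists (percentile 0.00), and 38 lay below the median of all genes. The lowest was Hoxa13 at 0.503, Hoxa1 was in the middle at 0.718 and the exception was Hoxb1 at 1.09. The low values covered all 4 clusters. On chromosome 6, from 52155367 to 52260880, the 11 Hoxa genes had a median of 0.662, while 12 flanking genes of at least 5 kb within 1 Mb had a median of 0.972. The 10 Hoxb genes on chromosome 11, from 96194361 to 96368253, had a median of 0.673 against 0.941 for their flanks. The 9 Hoxc genes on chromosome 15 had a median of 0.743 against 0.940, and the 9 Hoxd genes on chromosome 2 had 0.767 against 1.07. Members of a cluster are neighbours and not independent, but the list also stood apart when ranks were rotated along the genome so that neighbours stayed together (percentile 0.01).

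**Figure D3:**
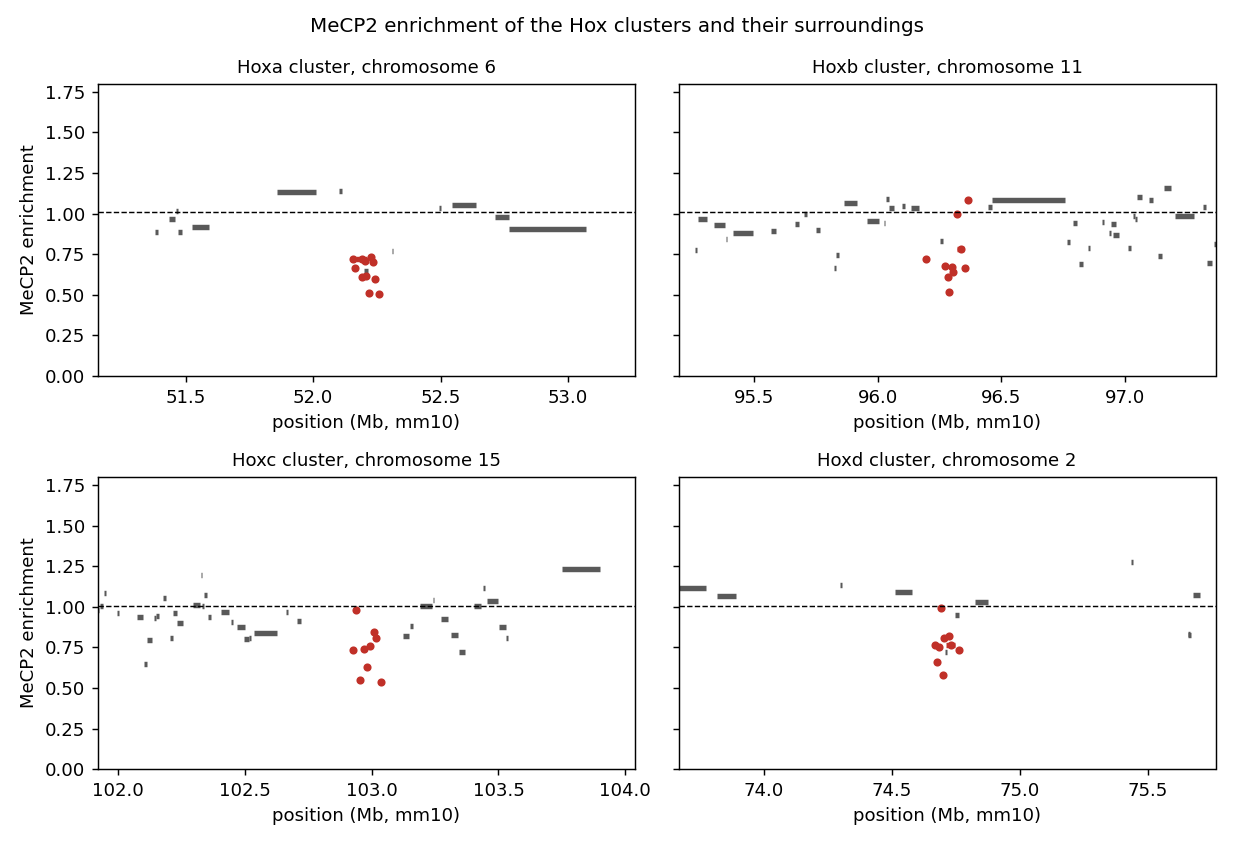
MeCP2 enrichment (vertical axes, the deposited value without unit) against position in Mb on mm10 for the 4 Hox clusters and 1 Mb on either side. Red points and segments are Hox genes, grey segments are other genes of at least 5 kb drawn to their length, and the dashed line is the median of all genes; cluster medians run from 0.662 for Hoxa to 0.767 for Hoxd, under flanking medians of 0.940 to 1.07.

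Chemosensory receptor genes, which serve smell and pheromone sensing in the nose, carried the highest enrichment of the fixed lists. The 1094 olfactory receptor genes had a median of 1.25, against 1.09 for length-matched random lists that themselves drew on these genes, and 910 lay above the median of all genes. The 296 vomeronasal receptor genes had a median of 1.35 against 1.04, and 265 lay above it. Both lists fell at percentile 100, and at 99.9 and 100 with ranks rotated along the genome. Single genes spread widely, from Olfr603 at 0.114 to Olfr707 at 4.60 and from Vmn1r117 at 0.336 to Vmn1r37 at 3.90. These coding genes are near 1 kb long or belong to families of close copies, so the value of any single receptor gene is uncertain.

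Major urinary protein, beta-defensin and clustered protocadherin genes lay above random lists, but not when ranks were rotated along the genome. The 20 major urinary protein genes, pheromone carriers made in the liver, had a median of 1.20 at percentile 99.99. They spread from Mup1 at 0.086 to Mup9 at 6.02, and near-identical copies make single members uncertain. The 41 beta-defensin genes, antimicrobial peptides of epithelia, had a median of 1.22 at percentile 99.98, from Defb45 at 0.848 to Defb4 at 1.63, and 36 lay above the median of all genes. The 58 clustered protocadherin genes, adhesion proteins that give neurons their surface identity, had a median of 1.11 at percentile 99.9, from Pcdhgc5 at 0.666 to Pcdhb6 at 1.86. By rotation these 3 lists were within the central 95%, at percentiles 95, 97.2 and 85.5. Members of the protocadherin list overlap each other, and those of at least 5 kb lay low instead, with a median of 0.954 at percentile 1.09. The 323 Zfp genes, mostly transcription factors with zinc fingers, had a median of 1.04 against 0.995 for random lists, at percentile 100. This difference of 0.046 was small, with 198 members above and 125 below the median of all genes. They ran from Zfp593 at 0.604 to Zfp433 at 1.47, and the list stayed above random lists under every alternative run.

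Ribosomal protein genes had a median of 0.914 over 68 genes at percentile 4.86, inside the range of random lists, from Rps28 at 0.614 to Rplp1 at 1.84. Without length matching the list was low (percentile 0.02), and among genes of at least 5 kb it lay at percentile 60.8. Replication-dependent histone genes had a median of 1.22 over 56 genes at percentile 90.4, from Hist1h2bm at 0.435 to Hist1h2ai at 5.89. Keratin-associated protein genes, structural proteins of hair, had a median of 1.19 over 52 genes at percentile 92.3, from Krtap11-1 at 0.305 to Krtap6-2 at 2.45. Both of these lists of short genes stood above random lists without length matching (100 for each) or without receptor genes in them (99.9 and 99.3). Without overlapping genes the histone list lay at percentile 32.95.

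MicroRNA and small nucleolar RNA genes had low medians and the widest interquartile ranges of the 26 lists, from 0.468 to 1.38 and from 0.393 to 1.24. The 866 microRNA genes had a median of 0.893 against 1.12 for length-matched random lists (percentile 0.00), from Mir184 at 0.032 to Mir133b at 9.0. The 89 small nucleolar RNA genes had a median of 0.836 against 1.14 (percentile 0.00), from Snord32a at 0.045 to Snora61 at 4.94. These features were 0.082 and 0.081 kb long at the median, shorter than nearly all other genes, so 10 length bins set them against longer genes. With 50 bins, the bins that held microRNA genes were on average 90.4% microRNA or small nucleolar RNA genes and those that held small nucleolar RNA genes 89.5%. The lists were then compared mostly with themselves, so their low position was not tested against other genes of equal length. MicroRNA symbols whose listed coordinates span at least 5 kb lay high, at percentile 99.7. With values of 0 or below kept, the medians of the microRNA and small nucleolar RNA lists fell to 0.737 and 0.701.

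Of the 26 lists, 8 lay above and 7 below the central 95% of random lists. The lists that stood apart in every alternative run numbered 5, namely granule cell, Hox, olfactory receptor, vomeronasal receptor and Zfp genes. With ranks rotated along the genome 5 lists stood above in place of 8.

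Gene length was compared with enrichment because long genes have been at the centre of work on MeCP2. Across genes the Spearman correlation was 0.011, and among genes of at least 5 kb it was 0.111; genes are not independent replicates. Genes under 5 kb had a median of 1.02, those of 5 to 20 kb 0.981, those of 20 to 100 kb 1.02 and those over 100 kb 1.02. Spread differed more than level. The 5905 genes under 5 kb ran from 0.468 at the 5th percentile to 1.85 at the 95th, against 0.768 and 1.24 for the 2226 genes over 100 kb.

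**Figure D4:**
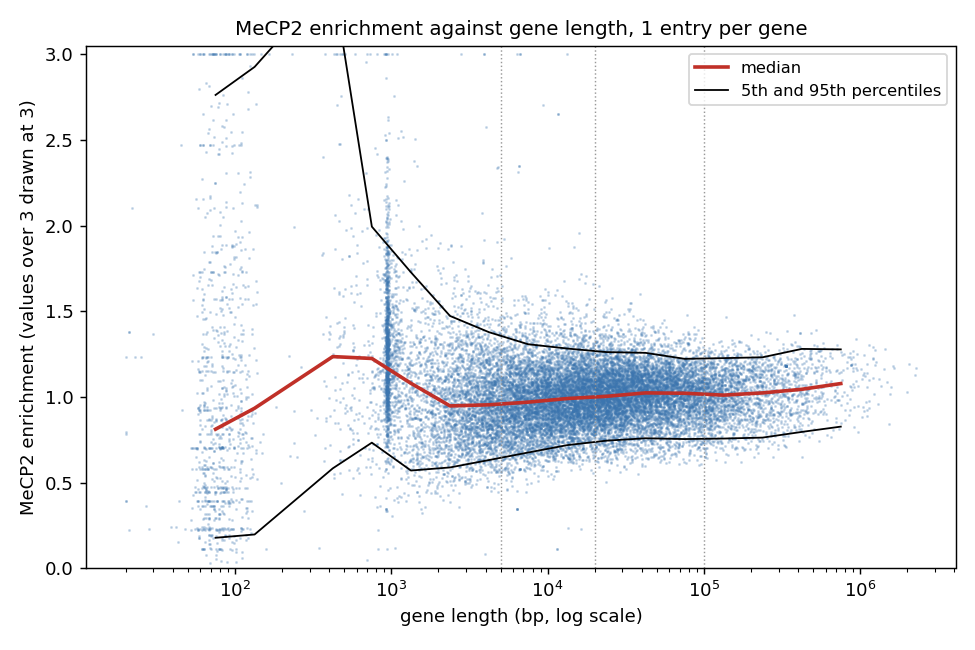
MeCP2 enrichment (vertical axis, the deposited value without unit, values over 3 drawn at 3) against gene length in bp on a log axis, for each of 22345 genes (points). The red line is the median and the black lines the 5th and 95th percentiles in steps of length, and dotted lines mark 5, 20 and 100 kb; the interquartile range is 0.457 under 5 kb, 0.225 from 5 to 20 kb, 0.192 from 20 to 100 kb and 0.208 over 100 kb.

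Neighbouring genes had similar MeCP2 enrichment. Over 19634 pairs of adjacent, non-overlapping genes the Spearman correlation across pairs was 0.500, against a highest value of 0.050 over 1000 random orders of genes within chromosomes. Among 9912 pairs more than 10 kb apart whose symbols began with different runs of letters it was 0.431, against at most 0.060 in random orders. The letter rule stands in for gene families and can miss copies with unlike names. Each gene was also set against the mean of the nearest non-overlapping gene of at least 5 kb on either side, which for a Hox gene can be another Hox gene. By this measure Hox genes lay below their nearest neighbours, with a median difference of -0.139 (percentile 0.02 of length-matched lists), a smaller gap than that between whole clusters and their surroundings. Granule cell genes also lay below their nearest neighbours, with a median difference of -0.096 (percentile 0.09). Olfactory and vomeronasal receptor genes lay above theirs, with median differences of 0.074 and 0.083 (both at percentile 100). The random lists for these differences did not keep neighbours together, so the percentiles of the clustered Hox and receptor genes may be too extreme. The comparison of genes on chromosome X with autosomal genes and that of enrichment with base composition were not analysed here.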

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

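The random lists with 50 bins, without receptor genes or without the filter, the rotation along the genome and the neighbour settings other than distance were chosen after the result was seen. No paired analysis was possible because the deposited table holds 1 value per transcript and no column per replicate. For the same reason the replicate block, DESeq2, other scalings, pseudocounts, an estimated correlation and leaving out a library were not run, and GC matching, base composition and chromosome X were not run either. Granule cell, Hox, olfactory receptor, vomeronasal receptor and Zfp lists stood apart in every alternative run, 8 lists were inside random lists in every one, and 13 changed in at least 1. Values that follow are percentiles. Some lists stayed inside random lists but crossed their middle: muscle without overlapping genes (96.83), histone without them (32.95), microglia and endothelium without them (22.24) and by rotation (43.60), glia (68.01) and ribosomal protein (60.83) among genes of at least 5 kb, and housekeeping without length matching (48.22). With genes of at least 5 kb, the liver list moved to 97.25, immediate early to 34.20, long synaptic to 97.41 and MeCP2-responsive to 30.77, while clustered protocadherins at 1.09 and microRNA genes at 99.74 turned to the other side. This setting leaves out the shorter members. Without length matching the liver list moved to 96.89, ribosomal protein to 0.02, and histone and keratin-associated lists to 100. Without overlapping genes the cortical list moved to 10.23, and with means over transcripts to 2.54. With 50 bins, long synaptic moved to 84.93. MicroRNA at 60.78 and small nucleolar RNA at 31.43 show nothing in this setting, because their bins consist mostly of these genes (90.4% and 89.5%), and small nucleolar RNA changed in no other setting. Without receptor genes, cortical moved to 2.79, immediate early to 3.88, histone to 99.92 and keratin-associated to 99.29, and without the filter keratin-associated moved to 97.58. With rotation, immediate early moved to 2.80, clustered protocadherin to 85.49, major urinary protein to 95 and beta-defensin to 97.22, and 5 lists in place of 8 stood above. The cause of these shifts was not tested. The length correlation was 0.111 among genes of at least 5 kb against 0.011 for all genes. The neighbour correlation ranged from 0.431 to 0.550. The unknown read number behind short genes limits what single values under 5 kb can show.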

Other observations

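A further 14 gene lists were written after the main results had been seen and before their own values were computed. Synaptic vesicle release genes were low, with a median of 0.835 over 20 genes (percentile 0.00 of length-matched random lists) and 18 below the median of all genes. Stx1b, a plasma membrane syntaxin of the release machinery, was lowest at 0.632, Unc13a, a vesicle priming factor, lay at 0.843, and the vesicle GTPase gene Rab3a was highest at 1.11. Of these genes Snap25 and Syt1 were also in the granule cell list. Developmental transcription factor genes, most of them silent in adult neurons, had a median of 0.906 over 95 genes (percentile 0.03), and respiratory chain genes had 0.921 over 82 genes (percentile 0.93), with Atp5d at 0.922. Voltage-gated potassium channel genes (0.908, percentile 3.18, 16 genes), proteasome genes (1.00, percentile 63.1, 38 genes), keratin genes (0.993, percentile 74.0, 47 genes) and interferon alpha genes (1.11, percentile 40.8, 13 genes) lay inside random lists. Kcnc3, a channel of fast-firing cerebellar neurons, was the lowest potassium channel gene at 0.625, and Kcnc2 the highest at 1.29.

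Of the same added lists, 5 further ones lay above random lists. Testis genes had a median of 1.17 over 25 genes (percentile 99.97), with the germ cell helicase gene Ddx4 at 1.17. Cytochrome P450 genes had 1.16 over 75 genes and serpin genes 1.12 over 49 genes, both at percentile 100. Natural killer lectin-like receptor genes had the highest median of any list, 1.38 over 29 genes, and 28 of them lay above the median of all genes, from Klrg2 at 0.989 to Klra18 at 1.57. Bitter taste receptor genes had 1.31 over 35 genes (percentile 99.0). The alternatives of the fixed lists were then applied to the added lists, and 10 of the 14 kept their position in every one that could be run. Developmental transcription factor genes were inside random lists among genes of at least 5 kb (percentile 4.41). Respiratory chain genes were inside in that setting (5.39), without receptor genes (2.53) and by rotation (2.64). Bitter taste receptor genes were inside without overlapping genes (92.4), with 50 bins (90.03) and by rotation (84.1), and potassium channel genes were low among genes of at least 5 kb (0.24) and by rotation (1.89). Chromosome medians ran from 0.937 on chromosome 11 to 1.09 on chromosome 13. Among genes of at least 5 kb, transcribed pseudogenes had a median of 1.11 over 113 genes and long noncoding RNA genes 1.04 over 1229, against 1.00 for 14859 protein-coding genes.

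The low enrichment of granule cell genes was weighed against gene length, against low chromosomal regions and against use of these genes in granule cells. Among genes of at least 5 kb the list fell at percentile 0.00, and its members lay below their flanking genes with a median difference of -0.096, both of which argue against length and against regional level as the whole cause. Use in granule cells was examined with receptor subunits: 15 subunits of granule cell synapses had a median of 0.928 and 24 used mainly elsewhere 1.03, a difference of -0.102 (random lists: -0.107 to 0.135). A criterion written before these values asked for granule subunits below percentile 2.5 and at least 0.05 below the others. The difference passed that margin, but the granule subunits fell at percentile 4.61, inside random lists. The criterion for use was therefore not met. With only 15 genes, 4 of them already in the granule cell list, this neither excludes nor accepts use. Housekeeping genes at percentile 71.6 and the low Hox genes are not what use alone would give, though use was assumed here and not measured. Other widely used genes differed among themselves, with respiratory chain genes at percentile 0.93, ribosomal protein genes at 4.86 and proteasome genes at 63.1. Low values were also not particular to the granule cell list. Its median lay -0.025 from that of cortical and interneuron genes, within random lists. Synaptic vesicle release genes had a median of 0.835. Transcription and DNA methylation were not measured in these data, so the explanation by use remains a hypothesis. Base composition was not analysed here and stays open as well.

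The high enrichment of olfactory and vomeronasal receptor genes was weighed against reads shared between close copies and against short gene length. Genes of other families that lie between receptor genes were high too, with a median of 1.207 over 36 genes against 1.00 for random lists (percentile 100); symbols of further receptor families were left out of this set after its members had been seen, and with them the median was 1.22 over 42 genes. The 166 receptor genes of at least 5 kb had a median of 1.336 against 0.999. The receptor genes of at least 5 kb argue against short length as the whole cause. Only the genes between receptors bear on shared reads. These were not screened for close copies, or for receptor genes inside their coordinates, and include Usp17ld at 1.889 and Usp17lc at 1.605. Mir466f-1, at 1.234, is listed from 12071790 to 12413554 on chromosome 19. The random lists for this set did not keep neighbours together either, so the set argues only weakly against shared reads as the whole cause. A regional level that takes in the genes between receptors may contribute, but olfactory and vomeronasal receptor genes also lay above their own flanking genes, by medians of 0.074 and 0.083, so it stays open together with base composition, repeats and methylation, which were not analysed here.

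The low medians of microRNA and small nucleolar RNA genes may come from few reads per feature. Of 878 such features of at most 150 bp, 336 had values that fit a single ratio, as when 1 of the 2 summed ratios is 0, and these had a median of 0.467. The other 542 had a median of 1.038, close to the 1.01 of all genes, and the longer genes that contain 553 of the features had a median of 0.972. This is what low read numbers would give, although leaving out values with a term of 0 itself raises the median. Features with a value of 0 or below were in neither group, which can only raise these medians further. The sum of 2 ratios, searched over small read numbers only, fitted 63.7% of short features, and no biological explanation was tested.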
